A study of Homo sapiens with 6 samples.

How the data were processed

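LNCaP and PC3 cells were each profiled with a METTL3 antibody, a PRMT5 antibody and a control, 1 library per group, 6 in all, with 100000 cells and 16 PCR cycles per library. Libraries were made with an in-situ ChIP kit, in which cells held on beads are incubated with a primary and a secondary antibody and a protein G-Tn5 transposase that cuts and tags chromatin where the antibody sits, and were sequenced on an Illumina instrument, per the labels' protocols. Per the submitters' processing notes the tools were bcl2fastq 2.17, Trimmomatic 0.33, Bowtie 1.1.1, MACS2 2.1.0 and ChIPseeker, whose version is not given in the sources used here, and the build was hg38. Their settings, duplicate removal and read shifting are not given in the sources used here. Each file is a list of peaks called on 1 library against the control of its own line, so peaks were not pooled over samples.

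The lists hold, for each peak, its position, a score, a fold, −log10 p, −log10 q and the summit. The score the authors deposited was 10 times the −log10 q, rounded down, within 1 unit in all entries. The fold (a ratio over the control's expected signal) and the −log10 p and −log10 q values are the authors' caller's own values, deposited per peak. They were used only to describe, rank or filter peaks within a list. The largest q in the 4 lists was 0.0495. Read counts and library depths are unknown, so the number of peaks in a list cannot be set against its depth, and a deeper library would give more peaks.

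From these files, entries on chromosomes 1 to 22, X and Y were kept, 173 of 199 for LNCaP METTL3, 980 of 1084 for LNCaP PRMT5, 7453 of 7500 for PC3 METTL3 and 1661 of 1721 for PC3 PRMT5. No entries of a list overlapped, so merging changed nothing. Gene positions came from a RefSeq gene table of GRCh38.p14, the same primary coordinates as hg38, with 59679 genes on these chromosomes, 20037 of them protein-coding. The table gives each gene's start and end but no strand, transcripts or exons, and no genome sequence was used here. The design had called for transcription start sites. In their place a peak counted as at a gene end when its summit lay within 3 kb of either end of a protein-coding gene, which takes in 3-prime ends too. For the same reason, exon, intron and UTR annotation, sequence motifs, repeat-masked alternatives and a single start site per gene were not run, and gene bodies with 5 kb on both sides replaced gene bodies with 5 kb upstream.

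Overlaps counted peaks of 1 list that share at least 1 bp with a peak of the other. They were compared with 1000 shuffles of the shorter list within each chromosome, inside the span from the outermost gene or peak and outside stretches of at least 2 Mb with no gene of any type, which stand in for assembly gaps. This left 2881 Mb to shuffle in and took out 206 Mb. The permutation p was one-sided for overlaps and two-sided for the share at gene ends. Because shuffled overlaps were near 0, shared peaks are given as counts and percent beside the shuffled mean and maximum, not as a fold. Intervals are exact (Clopper-Pearson) 95% binomial intervals and cover counting error only. Lists of a line share 1 control, and the cross pairs, which share neither antibody nor control, are given as a baseline. Differences in share between lists were tested with Fisher's exact test and differences in partner with an exact McNemar test; peaks, not replicates, are the units. p-values were adjusted by Benjamini-Hochberg within each family. With 1 library per group no spread between replicates could be measured, and no batch is named in the labels.

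A total of 24 gene lists with 594 names, 593 of them matched, were fixed before the data were examined; 22 lists of protein-coding genes were tested. They cover the m6A machinery, arginine methyltransferases and the methylosome, the spliceosome core, SR and hnRNP splicing regulators, ribosomal proteins, replication-dependent histones, androgen-regulated genes, luminal prostate, basal and mesenchymal genes, AP-1 and immediate early genes, E2F and cell cycle, DNA repair, p53 targets, unfolded protein and stress, mitochondrial respiration, interferon response, chromatin regulators, neuroendocrine genes and off-lineage markers of immune cells, neurons, hepatocytes and fibroblasts. The number of members with a peak at an end was compared with 10000 random lists of protein-coding genes matched on the decile of gene length. The 2 other lists, snRNA genes and abundant long noncoding RNA genes, were only counted. Named items followed a rule written before the data were examined. They are the 8 peaks of highest fold per list, the 6 shared regions per planned overlap with the largest smaller fold, up to 4 list members per list and library, PRMT5, WDR77, METTL3, METTL14, WTAP, KLK3 and MYC always, and up to 10 genes with an end peak in 3 or 4 lists.

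The procedures were tested on simulated data. With 40 planted shared peaks, each of the 6 overlap settings called all of 20 simulated pairs, and with none planted the PC3 METTL3 and PRMT5 setting called 2 of 20. With 30% of peaks planted at gene ends, all of 20 simulations were called for each list. With the members of 1 list weighted 10-fold, the list test called 9 of 20 simulations for LNCaP PRMT5, 12 for PC3 METTL3, 14 for PC3 PRMT5 and 0 for LNCaP METTL3, so it has little or no power at the size of the last list. Alternatives named before the data were examined were other overlap rules, stricter −log10 q (at least 3) and fold (at least 5), lists cut to equal length, shuffles within 2.5 Mb or between gene ends, windows of 1 kb and 5 kb, all gene types, and all contigs. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.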

Results

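Chromatin occupancy of PRMT5 and METTL3 was profiled in 2 human prostate cancer cell lines, LNCaP, an androgen-responsive line, and PC3, an androgen-independent line. PRMT5 is an arginine methyltransferase that places symmetric dimethyl marks on histones and splicing proteins. METTL3 is the catalytic subunit of the enzyme complex that writes N6-methyladenosine on RNA. The libraries came from an in-situ chromatin assay in which an antibody tethers Tn5 transposase to its target in permeabilised cells, with 100000 cells and 16 PCR cycles per library. Each line gave 1 METTL3 library, 1 PRMT5 library and 1 control library, 6 libraries in all. The control libraries are titled IgG, and their antibody field names a secondary antibody. The data used were 4 peak lists, 1 per antibody and line, each called against the control of the same line. The control libraries entered only through those calls and were not analysed here by themselves. The number of reads behind each list is unknown, and every group had 1 library. The tests that follow therefore describe these lists, not the cell lines or proteins at large, and intervals cover counting error only.

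The METTL3 list was the shortest in LNCaP and the longest in PC3. On chromosomes 1 to 22, X and Y of hg38 it held 173 peaks in LNCaP and 7453 in PC3, whereas the PRMT5 list held 980 peaks in LNCaP and 1661 in PC3. Numbers of peaks depend on read depth and were not tested. The fold of a peak over the control, as the authors' caller gave it, had a median of 6.22 for LNCaP METTL3, 6.56 for LNCaP PRMT5, 5.10 for PC3 METTL3 and 5.89 for PC3 PRMT5. Peaks with a fold of at least 10 made up 16.0% of the LNCaP PRMT5 list and 7.10% of the PC3 PRMT5 list. They made up 4.05% of the LNCaP METTL3 list and 0.174% of the PC3 METTL3 list. The median width of the PC3 METTL3 peaks, 292 bp, was also their smallest width. A threshold of 3 on the −log10 q kept 149 LNCaP METTL3, 782 LNCaP PRMT5, 4472 PC3 METTL3 and 1365 PC3 PRMT5 peaks.

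Of the 8 highest PRMT5 peaks of LNCaP, 6 lay within 3 kb of a gene end. The highest fold, 61.5, was at chromosome X, positions 318794 to 319195, beside GTPBP6, a gene of the pseudoautosomal region. It was followed by a peak of fold 60.8 at chromosome 14, positions 20461441 to 20462070, 298 bp from the end of PIP4P1, which encodes a lysosomal phosphoinositide phosphatase. A peak of fold 45.5 at chromosome 7, positions 874908 to 877217, lay beside GET4, and another of fold 38.5 at chromosome 21, positions 44517019 to 44517909, lay inside TSPEAR. Further peaks lay beside ATP6V1G1, a subunit of the vacuolar proton pump, with a fold of 32.4, beside GALNS, a lysosomal sulfatase, with a fold of 29.8, and beside SLC33A1, with a fold of 29.7. The remaining peak of the 8 highest, of fold 30.8, lay near the end of chromosome 4, 18.6 kb from DUX4.

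In PC3, 4 of the 8 highest PRMT5 peaks lay at chromosome ends, on X, 15, 9 and 12, with folds of 32.9, 28.8, 28.6 and 27.3. The one on chromosome 12 spanned positions 9928 to 10541. The highest PC3 PRMT5 peak, of fold 47.1 at chromosome 17, positions 113142 to 113466, was 24.3 kb from SCGB1C2, whose near-identical copy SCGB1C1 lies on chromosome 11, so reads there may belong to either place. A peak of fold 26.2 at chromosome 19, positions 40750250 to 40751049, lay between ACTMAP and SNRPA, which encodes a protein of the U1 splicing particle. The last of the 8 lay near CD300LB, with a fold of 24, and SLC44A2, with a fold of 23.9.

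In the LNCaP METTL3 list, 3 of the 8 highest peaks clustered beside TLE3, which encodes a transcriptional corepressor, on chromosome 15. The highest had a fold of 19.8 at positions 70099145 to 70099956, 1.81 kb beyond the end of the gene, and the other 2, at 88 bp and 4.19 kb from that end, had folds of 14.8 and 10.8. None of the 3 overlapped a peak of another list. A peak of fold 13.8 lay inside SLC6A11, a GABA transporter gene, and 1 of fold 10.5 lay inside SELP, which encodes P-selectin, at chromosome 1, positions 169621287 to 169621542. The SELP region had a peak in all 4 lists. In PC3, the 8 highest METTL3 peaks had folds of 10.3 to 13.8, and each lay at least 10.2 kb from the nearest end of a protein-coding gene. The highest, at chromosome 4, positions 166580033 to 166580694, was 153 kb from SPOCK3.

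PRMT5 peaks gathered at gene ends in both lines, and METTL3 peaks in PC3 lay there less often than shuffled peaks. The design called for transcription start sites; as the gene table used has no strand, a peak was counted when its summit lay within 3 kb of either end of a protein-coding gene. In LNCaP, 334 of 980 PRMT5 peaks met this, 34.1% (95% exact binomial interval 31.1 to 37.1), against a mean of 8.59% when the same peaks were shuffled within their chromosomes. In PC3, 475 of 1661 did, 28.6% (26.4 to 30.8), against 9.55% when shuffled. Both shares were above every shuffle (two-sided permutation p = 0.0020, the smallest that 1000 shuffles can give, adjusted p = 0.0040). The METTL3 share was 9.25% in LNCaP (5.38 to 14.6), 16 of 173, against 6.71% when shuffled (permutation p = 0.234). In PC3 it was 5.86% (5.34 to 6.42), 437 of 7453, below the shuffled 6.87% (permutation p = 0.0040, adjusted p = 0.0053). That LNCaP METTL3 share passed the threshold with a 5-kb window or with the ends of all gene types, and the PC3 METTL3 share no longer passed it with the ends of all gene types, where it was 15.7% against a shuffled 16.4%, or in the list cut to 173 peaks, where it was 4.62% against 6.81%. The shuffles spread peaks evenly along a chromosome, whereas PC3 METTL3 peaks lay unevenly. On chromosome 8, for example, stretches of 20 Mb held from 3 to 187 of them. Shuffles within 2.5 Mb were run for overlaps only. Whether the small PC3 METTL3 deficit comes from this uneven spread was therefore not tested.

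**Figure D1:**
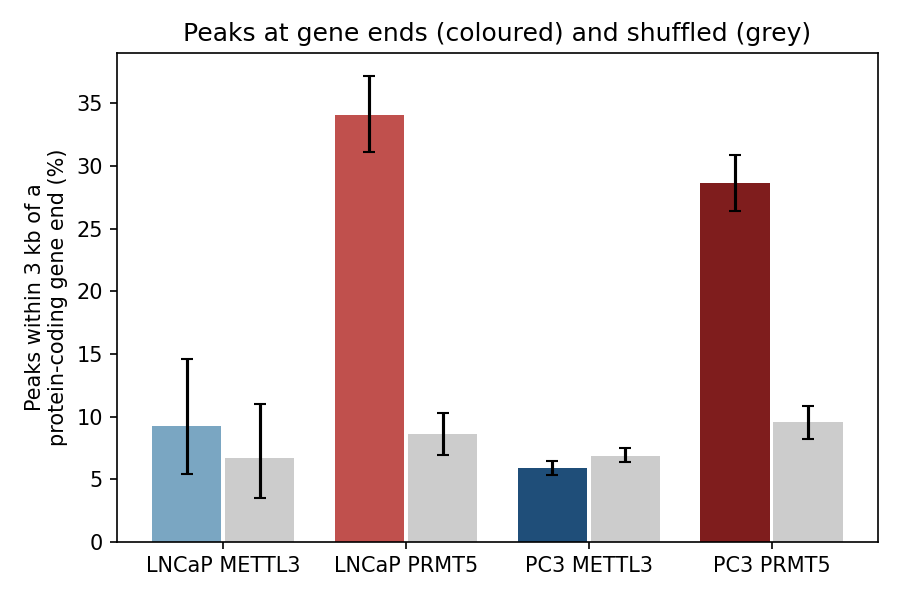
Percent of peaks whose summit lies within 3 kb of a protein-coding gene end (y axis), for the 4 peak lists (x axis). Coloured bars are the observed shares with exact binomial 95% intervals, and grey bars are the means of 1000 shuffles with the range that holds 95% of them; the PRMT5 bars stand at 34.1% and 28.6%, the METTL3 bars at 9.25% and 5.86%.

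Within each line the PRMT5 list held the higher share, by 24.8 percentage points in LNCaP (Fisher's exact test on peaks, adjusted p = 3.28e-12) and by 22.7 in PC3 (adjusted p = 1.06e-134). The odds ratios were 5.07 and 6.43, and a normal approximation called no difference between them. The LNCaP PRMT5 share exceeded the PC3 PRMT5 share by 5.48 points (Fisher's exact test, adjusted p = 0.0046). This order turned when both lists were cut to 173 peaks, with 31.8% in LNCaP (24.9 to 39.3) and 41.6% in PC3 (34.2 to 49.3). LNCaP stayed the higher in the other alternatives, and none of these differences was tested. Summits within 500 bp of a gene end made up 20.8% of LNCaP PRMT5 peaks, 10.9% of PC3 PRMT5 peaks, 2.31% of LNCaP METTL3 peaks and 0.859% of PC3 METTL3 peaks. Among LNCaP PRMT5 peaks the share at gene ends was 22.9% in the lowest quartile by fold and 50.2% in the highest. In PC3 those shares were 26.2% and 32.5%, with overlapping intervals.

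METTL3 and PRMT5 peaks coincided within each line, mostly away from gene ends. In LNCaP 73 of 980 PRMT5 peaks, 7.45% (5.88 to 9.28), overlapped a METTL3 peak by at least 1 bp, and these took in 42.2% of the 173 METTL3 peaks. Shuffled lists gave a mean of 0.032 and at most 2. In PC3 151 of 1661 PRMT5 peaks, 9.09% (7.75 to 10.6), overlapped a METTL3 peak, against a mean of 2.84 and at most 10 when shuffled, and these were 1.99% of the METTL3 peaks. With a fold of at least 5 required, the overlaps fell to 4.22% in LNCaP and 5.34% in PC3, and with lists of equal length they were 15% and 5.00%. Both overlaps were above every shuffle (one-sided permutation p = 0.000999, the smallest that 1000 shuffles can give). Only 8.22% of the shared LNCaP peaks and 6.62% of the shared PC3 peaks lay at gene ends. Repeat-prone places, such as chromosome ends and long gene-free stretches, held 23.3% and 7.28% of the shared peaks. They held 11.3% and 3.97% of all PRMT5 peaks of the same lines. Without such places the overlaps were 6.44% in LNCaP and 8.78% in PC3. Both lists of a line were called against the same control library, so part of the excess may come from places where that control was low, and no reads were at hand to simulate this. Pairs of lists that share neither antibody nor control were also above every shuffle, as given below. The shuffles therefore cannot tell sites of both proteins from places where any library gives peaks.

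The shared regions of LNCaP with the highest smaller fold lay inside SLC6A11 (chromosome 3, positions 10873466 to 10874004; fold 9.84 for PRMT5 and 13.8 for METTL3), 321 kb from EDEM1 (9.59 and 9.06), inside SELP (8.65 and 10.5), 12.7 kb from B4GALNT4 (8.42 and 9.28), and inside ZMYND11 and L3MBTL4 (both 7.85 for PRMT5). In PC3 they lay 809 kb from EDIL3 (chromosome 5, positions 85193929 to 85194163; fold 13.8 for PRMT5 and 10.2 for METTL3), 68.9 kb from MRPL14 (23.2 and 10.2), inside CREM, which encodes a cAMP-responsive transcription factor (8.60 and 8.46), 613 kb from TRIML1 (12.4 and 8.34), and inside XKR6 and TRPM2, a cation channel gene (both 7.95 for PRMT5).

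PRMT5 peaks recurred between the lines far more than METTL3 peaks did. Of 980 LNCaP PRMT5 peaks, 298 overlapped a PC3 PRMT5 peak, 30.4% (27.5 to 33.4), against a mean of 0.48 and at most 4 when shuffled, and 49.3% of the shared peaks lay at gene ends. Of 173 LNCaP METTL3 peaks, 16 overlapped a PC3 METTL3 peak, 9.25% (5.38 to 14.6), against a mean of 0.288 and at most 3 (both permutation p = 0.000999). With a fold of at least 5 required, the METTL3 overlap of the lines fell to 2 of 127, 1.57% (permutation p = 0.00999), and the PRMT5 overlap to 176 of 805, 21.9%. When at least 50% of both peaks had to overlap, the shares were 6.36% for METTL3 and 20.0% for PRMT5. The 2 pairs of lists that share neither antibody nor control serve as a baseline, and they also overlapped. PC3 PRMT5 covered 36 of the 173 LNCaP METTL3 peaks, 20.8% (15 to 27.6), and PC3 METTL3 covered 42 of the 980 LNCaP PRMT5 peaks, 4.29% (3.11 to 5.75), each with permutation p = 0.000999. With a fold of at least 5 required, these shares fell to 6.30% and 1.49%, and the first was 6.94% with lists of equal length. All 6 overlaps, with every peak kept, had an adjusted permutation p of 0.000999.

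**Figure D2:**
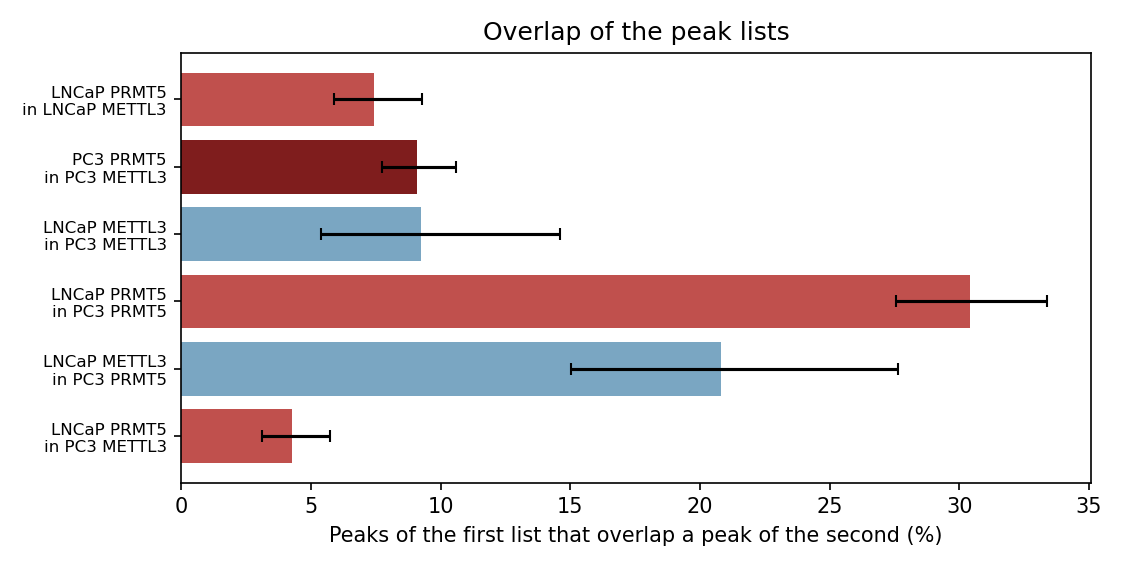
Percent of the peaks of the first-named list that overlap a peak of the second by at least 1 bp (x axis), for the 6 pairs of lists (y axis), with exact binomial 95% intervals. The PRMT5 pair across the lines stands highest at 30.4%, and the LNCaP METTL3 list shares 20.8% with PC3 PRMT5 but 9.25% with PC3 METTL3.

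The same peaks were compared for their partners with an exact McNemar test. LNCaP PRMT5 peaks were shared with PC3 PRMT5 in 30.4% and with LNCaP METTL3 in 7.45%. The lists of these partners hold 1661 and 173 peaks. So short a METTL3 list could hardly cover as many of the 980 peaks, so this difference decides nothing. PC3 PRMT5 peaks were shared with LNCaP PRMT5 in 17.7% and with PC3 METTL3 in 9.09%, although the PC3 METTL3 list is the longer (exact test, adjusted p = 6.33e-13). LNCaP METTL3 peaks were shared with LNCaP PRMT5 in 42.2%, with PC3 PRMT5 in 20.8% (exact test, adjusted p = 5.42e-07 for the difference) and with PC3 METTL3 in 9.25% (adjusted p = 0.000535 for PC3 PRMT5 against PC3 METTL3). The LNCaP METTL3 shares with PC3 PRMT5 and PC3 METTL3 were 6.30% and 1.57% at a fold of at least 5 and 6.94% and 3.47% in lists of equal length, where the difference was not tested. These tests depend on the lengths of the lists, and they were chosen after the overlaps were seen.

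The strongest PRMT5 regions shared by LNCaP and PC3 lay 6.95 kb from CD300LB (chromosome 17, positions 74513219 to 74515690; fold 22.3 and 24), 47 bp from the end of RMND1, a gene of mitochondrial translation (20.2 and 19.2), near the end of chromosome 4 by DUX4 (30.8 and 16.9), at the end of X (16.9 and 32.9), 113 bp from the end of WASHC2C, a subunit gene of the endosomal WASH complex (16.6 and 19), and 218 bp from the end of TRMO, a tRNA methyltransferase gene (16.0 and 16.6). WASHC2C has a near-identical copy, WASHC2A, so its reads may be shared. Of the METTL3 regions shared by both lines, the 6 with the highest smaller fold lay inside SLC10A7 (fold 6.06 and 8.26), SELP (10.5 and 5.10) and PRKAG2 (7.24 and 4.35), 321 kb from EDEM1 (9.06 and 4.58), 15.4 kb from B4GALT5 (4.11 and 5.05) and 12.6 kb from B4GALNT4 (9.28 and 4.10).

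At the level of genes, 385 protein-coding genes had a PRMT5 peak at an end in LNCaP and 485 in PC3, and 192 genes had one in both, against 10.8 for random genes of the same lengths (permutation p = 0.0001, the smallest that 10000 draws can give, adjusted p = 0.0002). The highest peaks of the lines overlapped at 161 of the 192 genes and lay apart at 31. Neighbouring genes can share a peak, and with each peak counted for its nearest gene only, 134 genes had one in both, against 6.22. Among the 192 were ATP6V0D1 (fold 18.4 in LNCaP and 12.9 in PC3), RRAGC (16.1 and 11.5), BAX (21.2 and 11.5) and GRN (11 and 10.1), named after their values were seen. METTL3 peaks marked 15 genes in LNCaP and 496 in PC3, 1 of them shared, against 0.362 for random genes (permutation test, adjusted p = 0.370). In LNCaP 10 genes had both a METTL3 and a PRMT5 peak, against 0.285 (permutation test, adjusted p = 0.0002), and in PC3 19 did, against 12.2 (adjusted p = 0.0552). Some of the 10 were neighbours on the same peaks, such as AMPD3 and RNF141, and 6 of the shared LNCaP PRMT5 peaks lay at gene ends. Random genes were drawn singly, so these tests can count 1 peak for several genes. The cross pairs shared 7 genes each, against 0.370 for LNCaP METTL3 with PC3 PRMT5 and 9.79 for LNCaP PRMT5 with PC3 METTL3. SERINC2 was the gene with a peak at an end in all 4 lists, with folds of 2.97 to 3.77. KISS1, a metastasis suppressor gene, and its neighbour GOLT1A shared a peak in 3 lists, with folds of 7.34 for LNCaP METTL3, 4.55 for LNCaP PRMT5 and 4.59 for PC3 PRMT5. PPP1R3F, FAM240C, AMPD3 with its neighbour RNF141, and 4 loci that carry only LOC symbols were the others found in 3 lists.

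None of the 22 gene lists fixed before the data were examined passed the test in any of the 4 libraries after adjustment over 88 tests, and 0, 0, 1 and 2 lists had an unadjusted permutation p below 0.05 in LNCaP METTL3, LNCaP PRMT5, PC3 METTL3 and PC3 PRMT5. The smallest p belonged to AP-1 and immediate early genes in PC3 PRMT5, where 4 of 24 had a peak against 0.780 for random lists (permutation p = 0.0074, adjusted p = 0.651). They were the phosphatase gene DUSP1 (fold 11), CCN1 (6.14), IER2 (5.92) and JUNB (4.93). In LNCaP PRMT5, 1 of the 24 had a peak, DUSP1 with a fold of 3.11. Splicing regulators of the SR and hnRNP families counted 3 of 28 in PC3 PRMT5, with KHDRBS1 at a fold of 8.38, HNRNPM at 5.01 and PTBP1 at 4.91 (permutation p = 0.0424, adjusted p = 0.976), and 2 of 28 in LNCaP PRMT5, with HNRNPL at 9.10 and PTBP1 at 5.30. They also counted 3 in PC3 METTL3, where HNRNPU had a fold of 6.83, SRSF11 6.52 and HNRNPL 4.70 (permutation p = 0.0328, adjusted p = 0.976). Among the 21 genes of the m6A machinery, LNCaP PRMT5 peaks lay at RBM15, an adaptor of the methyltransferase complex, with a fold of 16.6, and at the reader gene YTHDF1, with 7.85 (permutation p = 0.0599, adjusted p = 0.976). RBM15 also had a PC3 PRMT5 peak, of fold 3.96.

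Other lists held few members with peaks. The spliceosome core counted SNRPA at a fold of 2.98 in LNCaP PRMT5 and 26.2 in PC3 PRMT5, with SNRPE at 5.91 in PC3. The p53 targets counted the apoptosis gene BAX in both PRMT5 lists and PHLDA3 in PC3. Unfolded protein and stress genes counted DNAJB9 (fold 8.25 and 5.89) and DDIT3 (7.09 and 6.77) in both PRMT5 lists. Mitochondrial respiration counted ATP5MC1 in both PRMT5 lists (11 and 7.67, at peaks that do not overlap) and NDUFV2 in PC3. PC3 PRMT5 peaks further lay at the ribosomal protein gene RPL13A (5.92), the arginine methyltransferase gene CARM1 (4.82), MCM7 (5.19) and SIRT1 (5.78). Of the long noncoding RNA genes, given as counts only, TUG1 (21.8) and GAS5 (13.6) had LNCaP PRMT5 peaks. PC3 METTL3 peaks lay at PRMT3 and PRMT7 of the arginine methyltransferases, RPS3 and RPL4 of the ribosomal proteins, KLK2 and PMEPA1 of the androgen-regulated genes, ITGA2 and ZEB2 of the basal and mesenchymal genes, EGR2 and IER2 of the immediate early genes, and at CCNE2, RAD51C, ASNS, NDUFV1 and NCAM1, with folds of 3.79 to 6.83. They also lay at SPI1 and CYP3A4, markers of immune cells and hepatocytes, with folds of 4.40 and 5.61. No member of any list had a LNCaP METTL3 peak, where a self-test with members weighted 10-fold also called 0 of 20 simulated lists. The lists of histone, luminal prostate, interferon, fibroblast and snRNA genes had no member with a peak in any library.

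Of the genes named in advance, none had a peak at its ends in any list, namely PRMT5, WDR77, METTL3, METTL14, WTAP, KLK3 and the oncogene MYC. PRMT5, its cofactor gene WDR77, METTL3, METTL14 and WTAP lay 212 kb or more from the nearest peak. The nearest LNCaP PRMT5 peak to KLK3, which encodes prostate-specific antigen, was 36.0 kb away at chromosome 19, positions 50896658 to 50897064, with a fold of 16.7. A PC3 METTL3 peak of fold 6.83 lay 10.0 kb away. The nearest peak to MYC was a PC3 METTL3 peak 55.4 kb away.

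Chromosome 19, the most gene-dense chromosome, held the most PRMT5 peaks per Mb in both lines. Its number of peaks was 4.22 times that expected from its length in LNCaP (3.37 to 5.20) and 6.11 times in PC3 (5.32 to 6.97), and chromosome 21 followed in LNCaP with 2.88 and chromosome 17 in PC3 with 3.58. Per protein-coding gene the ranking turned, with chromosome 19 at 1.11 and 1.61, below chromosome 21 at 3.34 and 2.78 and, in LNCaP, Y at 5.84. PC3 METTL3 peaks were densest on chromosome 14, at 1.96 times the expected number (1.79 to 2.15), then on 8 at 1.88, 3 at 1.65 and 10 at 1.61, and sparse on Y at 0.0467, 13 at 0.324, 22 at 0.335 and X at 0.394. LNCaP METTL3 had 0 peaks on chromosome 19, and its densest chromosomes were Y at 3.35 times the expected number and 22 at 2.19, with 5 peaks each.

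**Figure D3:**
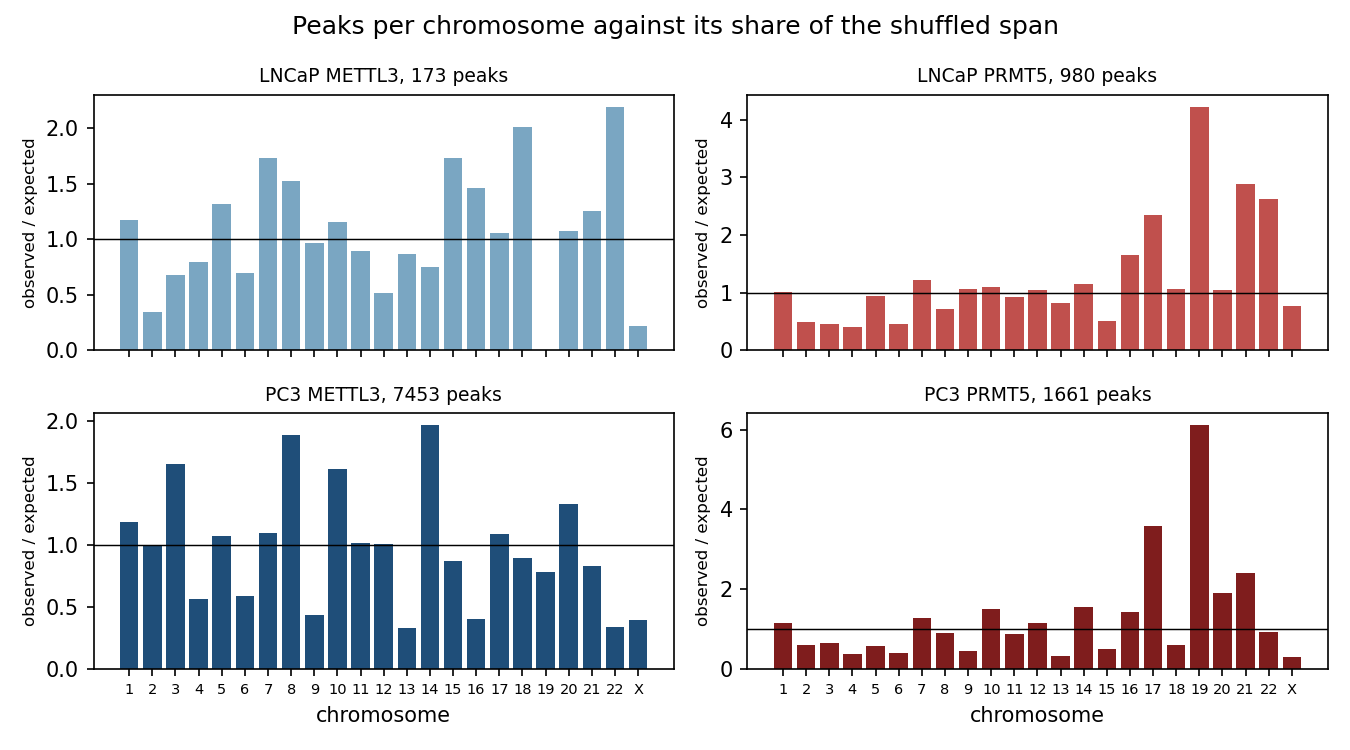
Observed over expected number of peaks (y axes, scaled separately, with a line at 1) for chromosomes 1 to 22 and X (x axes), 1 panel per list, with the expected number taken from the length of the span that peaks were shuffled in. The PRMT5 panels peak at chromosome 19, at 4.22 and 6.11, and the PC3 METTL3 panel at chromosome 14, at 1.96.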

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

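In LNCaP the METTL3 list had 0.177 times as many peaks as the PRMT5 list, and in PC3 it had 4.49 times as many. The contrast runs in opposite directions in the 2 lines, each with 1 library per antibody, and the difference was not tested.

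Entries that the comparisons left out, each called above the control of its line, lay outside the 24 chromosomes. On the mitochondrial genome there were 8 in LNCaP PRMT5, with a fold of up to 3.17, and 3 in LNCaP METTL3, with a fold of up to 1.71, and PC3 had 0 in either list. On the other contigs outside the 24 chromosomes there were 96 in LNCaP PRMT5, 60 in PC3 PRMT5, 47 in PC3 METTL3 and 23 in LNCaP METTL3, with a highest fold of 11.3, 8.02, 11.5 and 11.4. The controls' own levels there were not analysed, and no explanation was tested.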

How the results depend on the processing

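The alternative without peaks at repeat-prone places (chromosome ends, long gene-free stretches and their flanks, Y, mitochondrial pseudogenes and rRNA genes) and those for lysosomal genes and for genes shared by the PRMT5 lists were chosen after seeing the data; the others were named before. Of 146 alternative values, 136 kept the direction and side of the threshold, or stayed within the interval or 1.5 times the count of the reported value. Some of the 136 could hardly move. Counting every entry changed no list, as no entries overlapped, and 6 values were LNCaP METTL3 gene lists, where the test had little or no power. All 6 overlaps stayed above the shuffled mean with a permutation p under 0.05 in all of their alternatives, but each moved by over 1.5 times in some. The METTL3 overlap of LNCaP and PC3 ran from 1.57% to 9.80%, and its lowest value, 2 of 127 at a fold of at least 5, equalled the highest shuffled count. The overlap of LNCaP METTL3 with PC3 PRMT5 ran from 6.30% to 20.8%, that of LNCaP PRMT5 with PC3 METTL3 from 1.49% to 4.29%, and those of PRMT5 with METTL3 from 4.22% to 15% in LNCaP and from 5.00% to 9.09% in PC3. The PRMT5 overlap of the lines ran from 20.0% to 30.6%. Both PRMT5 shares at gene ends kept their calls, and they ran from 26.2% to 51.3% in LNCaP and from 16.3% to 41.6% in PC3 as the window, gene type or length of the list changed. No gene list passed under any alternative.

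The LNCaP METTL3 share at gene ends rose past the threshold at 5 kb (16.2%) and with the ends of all gene types (27.7%). The PC3 METTL3 share lost its call with the ends of all gene types (15.7%) and in the list cut to the shortest, 173 peaks (4.62%), where fewer peaks were tested. PC3 METTL3 kept 4472 peaks with a −log10 q of at least 3 and 4407 with a fold of at least 5. Per protein-coding gene, the excess of the chromosome densest by length became 1.11 on 19 for LNCaP PRMT5, 1.61 on 19 for PC3 PRMT5 and 9.19 on Y for LNCaP METTL3, against 3.35 by length there; with a −log10 q of at least 3 it became 2.28 on 14 for PC3 METTL3. Except where the construction shows it, the cause was not tested. Repeat-masked alternatives, a single start site per gene and all motif alternatives were not run. METTL3 and PRMT5 are paired by cell line, and they were compared within each line; no test over the 2 pairs was run. Unknown depth limits every statement on numbers of peaks.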

Other observations

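Among the tests in this part, the share of lysosomal genes with METTL3 peaks was predicted before it was computed; the others were chosen after the result was seen, and the lists of lysosomal and added control genes were written after the genes with PRMT5 peaks had been read. PRMT5 peaks in both lines lay at the ends of genes for lysosomes. Of 158 lysosomal and autophagy genes, 35 had a PRMT5 peak at an end in LNCaP, 22.2% (15.9 to 29.4), and 29 in PC3, 18.4% (12.7 to 25.3), against 1.92% and 2.42% of all protein-coding genes. These intervals treat genes as independent, although genes can share a peak, as BLOC1S1 and CD63 did in PC3. With each peak counted for its nearest gene only, 30 of the 158 had one in LNCaP and 23 in PC3. Random lists then gave means of 2.55 and 3.23. The vacuolar proton pump counted 5 of 17 subunit genes in each line, among them ATP6V0D1 (fold 18.4 in LNCaP and 12.9 in PC3), ATP6V0C (9.96 and 12.3) and ATP6V1G1 (32.4 and 5.43). Lysosomal enzymes counted 10 and 8 of 51, including the sulfatase gene GALNS (29.8 and 10.8) and the sialidase gene NEU1 (6.92 and 10.4). Lysosomal membrane genes counted 9 and 8 of 30, including PIP4P1 (60.8 and 10.4), the chloride transporter gene CLCN6 (23.4 and 7.33), the calcium channel gene MCOLN1 (17 and 6.31), CLN3 (12.7 and 5.54) and LAMP1 (6.58 and 16.5). The Ragulator, Rag, FLCN and BORC genes, which tie lysosomes to mTORC1 signalling and movement, counted 6 and 5 of 23, including RRAGC (16.1 and 11.5), FNIP1 (10.3 and 8.83) and LAMTOR1 (23.8 and 2.54). Autophagy genes counted 5 and 3 of 37, including VPS33A (5.37 and 19.8), and unlike the other 4 classes their PC3 count did not exceed that of random lists past the threshold (0.861 on average, permutation test, adjusted p = 0.195). Of the 158, 25 had a peak in both PRMT5 lists, against 1.67 for random lists, and at 21 of these the highest peaks of the lines overlapped. At MCOLN1, ATP6V0C, ATP6V0B and BLOC1S1 they lay apart, the MCOLN1 peak 7 bp from its end in LNCaP and 1130 bp from an end in PC3.

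Chance as the source of the lysosomal pattern stays open, since the list was written after the gene names had been seen, and the permutation p of 0.0001, the smallest that 10000 random lists can give, therefore decides nothing. The housekeeping controls were 217 genes of ribosomal proteins, mitochondrial ribosome and respiration, spliceosome, proteasome, and coat and exocyst proteins. Of these, 1.38% had a PRMT5 peak in LNCaP (0.286 to 3.99) and 4.15% in PC3 (1.91 to 7.73). Both intervals hold the share of all protein-coding genes, 1.92% and 2.42%, so this set showed no excess. Whether the lysosomal share exceeds that of housekeeping promoters is not decided by this. The lysosomal list and part of the controls were written after the genes with PRMT5 peaks had been read. A property of any library called against the same control could be examined in PC3 only, and with limits. METTL3 there marked a similar number of genes but only 1.27% of the lysosomal ones (0.154 to 4.50). Of all protein-coding genes it marked 2.48%, so it showed no excess at the lysosomal ones. The lower limit of the PC3 PRMT5 share was 12.7%, or 9.46% with each peak counted for its nearest gene only. The late writing of the list may have raised that PRMT5 share, so the gap between the antibodies decides nothing by itself. However, 0.859% of PC3 METTL3 summits lay within 500 bp of a gene end, against 10.9% for PC3 PRMT5. A list with few peaks so close to gene ends may miss a low control there. The LNCaP METTL3 list marked 15 genes, too few to decide. What also stays open is whether the antibody saw PRMT5 or another protein at these genes, since no PRMT5-depleted library was analysed here. The MiT/TFE transcription factors, which bind the promoters of many lysosomal genes, may be present at the same sites, as a hypothesis that would need the motif test not run here.

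PRMT5 peaks also marked chromosome ends, with 36 in LNCaP and 32 in PC3 beyond or within 50 kb of a chromosome's outermost gene, on 20 chromosomes each, against shuffled means of 1.17 and 1.87 (both permutation p = 0.000999, the smallest that 1000 shuffles can give); 32 and 31 of them overlapped a peak of another list. METTL3 had 4 of 173 in LNCaP against 0.179 (permutation p = 0.002), a share of 2.31% (0.633 to 5.81) whose interval overlaps that of LNCaP PRMT5, 3.67% (2.59 to 5.05), and 8 of 7453 in PC3 against 6.43. These 4 LNCaP METTL3 peaks had a median fold of 1.74, against 6.22 at the other peaks of that list. Weak calls near the threshold are argued against by a median −log10 q of 197.8 in LNCaP and 382 in PC3 at these peaks, against 5.94 and 4.83 at the other PRMT5 peaks. A control library short of reads there would raise METTL3 too, which in PC3 is argued against by the long METTL3 list, whose peaks overlapped 6.25% of these peaks (upper limit 20.8%), with the limit that its depth is unknown; the 11.1% in LNCaP decides nothing, as that METTL3 list is short. Reads of telomeric repeats placed at several chromosome ends stay open, as does binding, and no biological explanation was tested.

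PC3 METTL3 peaks were unevenly spread over chromosomes. Over 147 bins of 20 Mb their density rose with the log2 ratio of PC3 to LNCaP PRMT5 peaks (Spearman rho = 0.506, interval 0.369 to 0.622, Pearson r = 0.452, two-sided permutation p = 0.0005, the smallest that 2000 permutations can give; rho = 0.496 without chromosomes 14 and 19). This is what gains and losses of the PC3 genome could give, since both PC3 libraries would follow copy number; the control they share could give it too. Gene density as the whole cause is argued against, since per protein-coding gene chromosome 14 stood at 2.01 and the spread over 23 chromosomes (SD of log2 observed over expected) was 1.01 (0.695 to 1.24), against an upper limit of 0.121 in simulations by number of genes. Whether the correction widened that spread was undecided (1.33 times the spread by length, 0.979 to 1.76), bins had rho = 0.0369 with gene density (-0.132 to 0.201), neighbouring bins are not independent, and copy number was not measured.

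The LNCaP METTL3 list shared 42.2% of its peaks with LNCaP PRMT5, and 9 of its 173 peaks overlapped all 3 other lists.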
